A study of Mus musculus with 20 samples.

How the data were processed

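Total RNA of mouse brain progenitor cell lines was measured on 20 single-colour Affymetrix oligonucleotide arrays, 1 sample per array. Per the labels, 5 samples were control embryonic progenitors, 5 were embryonic progenitors after transduction, a genetic modification, 5 were control postnatal progenitors and 5 were postnatal progenitors after transformation. The labels do not name the introduced sequence or the transforming agent. They number the samples of a group but do not say that these came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

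The deposited values were linear intensities, 1 signal for each of 45101 probe sets on each array. The software, background correction and normalization behind them are not given in the sources used here. The mean of each array after trimming 2% of the values at each end lay between 2499.18 and 2499.28, a spread of 0.00394%, which is what scaling each array by a single factor gives, so the intensities were used as deposited. The table has no detection flag. A background level was therefore taken on each array as the 95th percentile of 27 control probe sets for bacterial transcripts, and it ranged from 107 to 221. Between 61.3% and 73.2% of the probe sets of an array lay above it. For arrays the precision is limited by their number, here 5 per group.

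The platform annotation supplied with the table gave 1 gene symbol to 34958 probe sets and several to 932, and it did not list 9160 of the 45037 probe sets left after removal of 64 control probe sets. Probe sets with several symbols were not named. Each of 18193 genes was represented by the single-symbol probe set with the highest mean log2 value over the 20 arrays, and 9011 of them had more than 1 probe set. Of the 18193 symbols, 18145 were found in a RefSeq gene table of assembly GRCm38.p6, which was used only for chromosome and gene order. None of the 190 pairs of arrays held identical values.

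Values were analysed as log2(signal + 16), which understates the change of dim genes. A linear model with 4 group means was fitted over all 20 arrays with limma 3.58.1 (lmFit and eBayes with an intensity trend) in R 4.3.3, with the data.table package (version 1.17.8) for reading. The test was two-sided, with Benjamini-Hochberg adjustment over all genes. A gene was called changed at an adjusted p under 0.05 and a change of at least 2-fold. Log2 changes are given with the standard error of that fit, signals as mean and SD over 5 arrays. Where a gene lay below background on all 5 arrays of a group, the fold is a lower bound, the mean log2 signal of the brighter group against the mean log2 of the higher of the background level and the signal itself in the dimmer group. No fold is given where both groups lay below background. Where a gene lay above background on 1 to 3 of the 5 arrays of a group, its fitted log2 change depends on the offset, so the mean signals and that number of arrays are given, and rankings that hold such genes are called fitted. Genes on 4 arrays keep their log2 change, with the number. List medians were also computed with such genes at their bound, and where this moved a printed median both are given. For the difference of responses each response was taken at its bound, or at 0 where both its groups lay below background, which gives no bound of the difference.

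The 5 comparisons were embryonic transduced against embryonic control, postnatal transformed against postnatal control, the difference between these responses as an interaction term, and the age comparisons of the control and of the modified cells. The age comparisons also hold any difference in region of origin, culture or preparation. That of the modified cells and the difference of responses also hold any difference between transduction and transformation. The groups, the tests of these comparisons, most alternatives, 31 gene lists and the rule for named genes were fixed before the data were examined. Leaving out postnatal control arrays 4 and 5 was chosen after seeing the data. Other alternatives and tests chosen afterwards are named as such below. Named genes were the 8 largest rises and 8 largest falls of each response among called genes whose groups did not overlap, and the 5 largest each way in the other comparisons. Clone names were passed over. Up to 4 members with the smallest p were eligible from each described list, and 9 measured genes of glioma biology were given in the responses whatever their value. Hras and Trp53, also in that rule, are not analysed here. Genes changed in both responses were ranked by the smaller of their changes, and 5 were named each way. Lists were tested with camera at a preset correlation between genes of 0.01, two-sided, with adjustment over the lists of a comparison, and again with an estimated correlation. Of 473 genes on the lists, 37 had no single-symbol probe set.

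The model was tested on simulated data before use. Independent normal noise was drawn with the residual SD of each of the 18193 genes, and 50 genes were changed at each of 4 sizes. The changed genes were taken from those above a set mean level, so recovery of dim genes was not tested. At an adjusted p under 0.05, 72.0% of genes changed by 1 on the log2 scale were recovered in the simulated embryonic response, 86.0% at 1.5 and 98.0% at 3, with 8 false calls. The 2-fold threshold was not applied in any simulated comparison, so these are not the shares that would be called. The median estimate of the genes changed by 1 was 0.98 there, which is under that threshold. For the simulated postnatal response the shares were 72.0%, 94.0% and 100%, with 6 false calls. In each of the 5 comparisons camera called all 3 lists that had been shifted, and in the comparison of the modified cells it also called 1 of 28 others. The noise was independent between genes, so this does not cover lists of correlated genes, such as mitosis with an estimated correlation of 0.985. The other comparisons recovered between 68.0% and 82.0% of genes changed by 1, with 8 false calls for the difference of responses, 18 for the controls and 12 for the modified cells.

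Alternatives covered scaling, dim genes, the choice of probe set, the fold threshold, the variance model, array weights, the replicate number as a block, the arrays in the fit, the offset and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.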

Results

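The 20 arrays fell into 4 groups of 5, control and transduced embryonic progenitors and control and transformed postnatal progenitors of the mouse brain. Glial progenitors are dividing precursors of astrocytes and oligodendrocytes. The transcription factors Olig2 and Sox2, which occur in such precursors, were bright in every group, with mean signals for Olig2 between 37229 and 70639 and for Sox2 between 36853 and 61414. The sample labels name only progenitors, and these genes alone do not settle their type. Arrays of a group correlated across genes with r between 0.947 and 0.970. The median SD of a gene within a group was 0.11 on the log2 scale in embryonic control, 0.13 in embryonic transduced, 0.20 in postnatal control and 0.10 in postnatal transformed. Within postnatal control, arrays 4 and 5 read apart from the other arrays for proliferation genes. Mki67, a marker of cycling cells, had signals of 37266, 34816, 35822, 5929 and 4351 on arrays 1 to 5. The log2 ratios of 3' to 5' control probe sets, a sign of RNA quality, differed between groups. For Gapdh the difference was 0.08 in the embryonic response, -0.09 in the postnatal response, -0.08 between the controls and -0.25 between the modified groups, with exact permutation adjusted p between 0.0119 and 0.0346. For Actb it was 0.10, 0.03, -0.07 and -0.14, and all but the postnatal response (exact permutation adjusted p = 0.198) had an adjusted p of 0.0119.

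**Figure D1:**
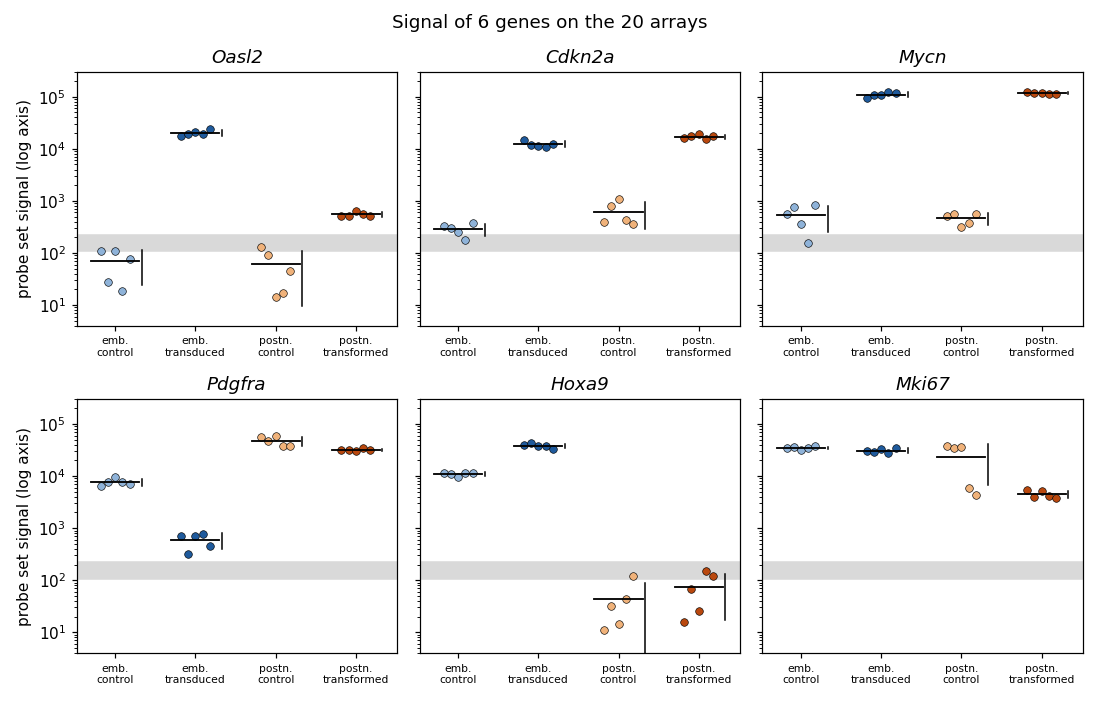
Probe set signal on a log axis for 6 genes on each of the 20 arrays, by group (points, single arrays; horizontal line, mean of 5; vertical line, SD, clipped where it passes the lower end of the axis; grey band, range of the background levels of the arrays). Oasl2 reached a mean of 20300 in embryonic transduced and 550 in postnatal transformed, Mycn 110118 and 117230 in the modified groups, and the highest signal of the Hoxa9 probe set shown on a postnatal array was 149.

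Transduced embryonic progenitors had higher interferon response and antigen presentation genes than their controls, and lower oligodendrocyte progenitor and neuronal genes. Each group had 5 arrays. Oasl2, an interferon-induced antiviral gene, rose from background, at least 121-fold. Ifi27l2a (at least 74.1-fold), Usp18 (mean signal from 130 to 16068) and Xaf1 (122 to 10764), also interferon-induced, rose with it, although the second Xaf1 probe set did not. The other genes among the 8 largest fitted rises were Mycn (7.85 ± 0.28 on the log2 scale), Ndrg1 (204 to 30457), the activity-regulated gene Arc (at least 69.3-fold) and the collagen prolyl hydroxylase P4ha2 (94.0 to 8871). In embryonic control, Mycn was above background on 4 of 5 arrays, Usp18 and Ndrg1 on 3, Xaf1 on 2 and P4ha2 on 1, so the size of these changes is not exact. Of the interferon response list, 16 of 17 measured genes rose and none fell (median 4.05; camera adjusted p = 2.57e-11, and 0.000466 with an estimated correlation), the same count when adjusted over the list alone. Irf9, a subunit of the interferon-activated transcription factor, rose by 4.05 ± 0.17 and Bst2 by 4.75 ± 0.25. All 10 genes of MHC class I presentation rose, also when adjusted over the list alone (adjusted p = 0.00156 with an estimated correlation), among them the peptide transporter Tap1 (4.22 ± 0.19) and H2-D1 (2.07 ± 0.08).

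The largest fitted falls in the embryonic cells were in Rps4l (at least 54.9-fold), the protocadherin Pcdh11x (mean signal from 6220 to 66.7), Anxa6 (11108 to 133), the glutamate receptor Grm5 (7068 to 114), Neto1 (8528 to 125), Elfn1 (4975 to 93.8), Brinp3 (at least 18.7-fold) and Tceal1 (at least 27.6-fold). Of the 5 given as signals, each was above background on 1 or 2 of 5 transduced arrays. In the oligodendrocyte progenitor list 10 of 15 genes fell and none rose, 11 when adjusted over the list alone (median -1.80; adjusted p = 0.00156 with an estimated correlation). Lhfpl3 fell by 5.06 ± 0.12, Sox6 by 3.31 ± 0.13 and the growth factor receptor Pdgfra, which marks these precursors, by 3.70 ± 0.19, from a mean signal of 7629 to 596. Of the neuron list, 12 of 15 genes fell and 1 rose, the same counts when adjusted over the list alone (adjusted p = 0.000387 with an estimated correlation). The growth cone gene Gap43 fell by 4.63 ± 0.14 and Map2 by 1.33 ± 0.05, whereas Gad1, which makes the transmitter GABA, rose from 177, above background on 3 of 5 arrays, to 1546.

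Immediate early genes, which respond within minutes to growth signals, rose in 9 of 12 cases with none lower, as when adjusted over the list alone (adjusted p = 0.0122 with an estimated correlation), with Klf4 higher by 5.31 ± 0.25 and Junb by 3.84 ± 0.17. In the hypoxia and glycolysis list 10 of 17 genes rose and 1 fell, 11 and 1 when adjusted over the list alone (adjusted p = 0.0263 with an estimated correlation), including Vegfa (3.07 ± 0.18) and hexokinase Hk1 (1.18 ± 0.07). Of 4 sex-linked transcripts, all 4 fell (adjusted p = 0.0107 with an estimated correlation). The Y-linked Eif2s3y fell at least 22.5-fold, Kdm5d from 3003 to 90.6, above background on 1 transduced array, and Uty from 1050 to 208. Xist, the transcript that silences an X chromosome in female cells, fell by 2.44 ± 0.12. The tests of 7 further lists passed at the preset correlation and were lost with an estimated one. Among them were the proneural glioma markers, 4 of 11 lower (adjusted p = 0.109 with an estimated correlation), with Dll3 at -4.28 and Nkx2-2 reading 7800 and 239, above background on 3 of 5 transduced arrays. Another was ERK pathway output, 6 of 18 higher and 1 lower (adjusted p = 0.591 with an estimated correlation), with Dusp4 at 2.93 and Ccnd1 at -1.91.

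In total 2611 of 18193 genes changed, 1567 higher and 1044 lower, of which 2206 had groups that did not overlap. The share of rises, 60.0% as deposited, was 51.2% after quantile normalization and 53.25% after centring on the 75th percentile. Among all 18193 genes, 6331 had groups without overlap, where chance alone gives 0.794% of genes. The called genes were selected by their difference, so their lack of overlap is no separate evidence. The tumour suppressor Cdkn2a, above background on 4 of 5 control arrays, rose by 5.37 ± 0.24 and the cell cycle inhibitor Cdkn1a by 2.25 ± 0.42. Olig2 differed by -0.93 ± 0.06, Sox2 by 0.01 ± 0.07, Nes by -0.18 ± 0.36 and Mki67 by -0.18 ± 0.44, none of them called, although Olig2 passed 2-fold after 75th percentile centring (-1.02). Gfap, below background in embryonic control, read 140 and 274 and was not called. Egfr was not called by its representing probe set (-0.45 ± 0.19), but its other probe sets ranged from -3.96 to 0.00081, and the mean of all gave -1.31. The Mycn rise rested on 1 of 3 probe sets, from 529 to 110118, while the others gave 0.95 ± 0.23 and 1.26 ± 0.36.

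Transformed postnatal progenitors also showed higher interferon and antigen presentation genes, together with amino acid and unfolded protein stress genes. The 8 largest fitted rises were in Wfdc18 (at least 124-fold), Mycn (7.96 ± 0.28), the protease inhibitor Serpina3n (mean signal from 149 to 16020), the synaptotagmin Syt4 (6.94 ± 0.45), Tcim (118 to 11955), the procollagen processing enhancer Pcolce (168 to 13514), the hormone receptor Pth2r (93.2 to 8672) and the ATP-gated channel P2rx3 (6.49 ± 0.27). In postnatal control, P2rx3 was above background on 4 of 5 arrays, Pcolce on 3, Serpina3n and Tcim on 2 and Pth2r on 1. The 8 largest fitted falls were in the imprinted cell cycle inhibitor Cdkn1c (at least 39.4-fold), the caveolae gene Cav1 (5154 to 110), Parvb (at least 9.66-fold), Zic1 (at least 9.37-fold), Dmrtb1 (-5.35 ± 0.35), Sncaip (2534 to 72.0), Dusp26 (1957 to 65.6) and Pla2g7 (-5.15 ± 0.52). In postnatal transformed cells, Dmrtb1 was above background on 4 of 5 arrays, Sncaip on 2 and Cav1 and Dusp26 on 1.

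Of the interferon response list, 14 of 17 genes rose and none fell, as when adjusted over the list alone (median 2.68, or 2.27 with genes at background at their bound; adjusted p = 0.00753 with an estimated correlation), with Ddx58, a sensor of viral RNA, higher by 2.75 ± 0.14 and the chemokine Cxcl10, above background on 1 of 5 control arrays, reading 91.6 and 1401. In MHC class I presentation 9 of 10 genes rose, as when adjusted over the list alone (adjusted p = 0.0222 with an estimated correlation), with H2-K1 at 2.85 ± 0.10 and B2m at 1.76 ± 0.09. In the list of unfolded protein and amino acid stress 8 of 15 genes rose and none fell, as when adjusted over the list alone (adjusted p = 0.00753 with an estimated correlation), led by the stress transcription factor Ddit3 (3.44 ± 0.12), while Chac1 rose by 3.11 ± 0.18. Myc targets and ribosome biogenesis fell as a list (median -0.63, adjusted p = 0.0262 with an estimated correlation), with 3 of 17 genes called lower, among them Gnl3 (-1.51 ± 0.06) and Cad (-1.66 ± 0.10). In these cells 1 Mycn probe set read 117230, while the others differed from control by only 0.58 ± 0.23 and 0.62 ± 0.36. Without control arrays 4 and 5 the call of the Myc target list was lost with an estimated correlation (adjusted p = 0.0635).

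In the mitosis list 15 of 19 genes fell, 16 when adjusted over the list alone, with Mki67 at -1.88 ± 0.44 and Kif11 at -1.87 ± 0.44, and in DNA replication 13 of 21, as when adjusted over the list alone, with Mcm7 at -1.38 ± 0.23. Neither call held with an estimated correlation (adjusted p = 0.665 and 0.587). The mean log2 of the mitosis list was 13.97, 13.90, 13.95, 11.11 and 10.996 on postnatal control arrays 1 to 5 and between 11.35 and 11.58 on the transformed arrays. Without control arrays 4 and 5, all 19 mitosis and all 21 DNA replication genes fell (adjusted p = 0.0102 for each with an estimated correlation). These arrays had been set apart for their low proliferation genes, so that outcome follows from leaving them out and is no separate evidence. Other lists passed only at the preset correlation. ERK pathway output was higher in 11 of 18 genes and lower in 2 (adjusted p = 0.257 with an estimated correlation), with Dusp4 at 4.47 and Egr1 at -2.11. Hox genes were higher in 9 of 24 cases (adjusted p = 0.066 with an estimated correlation), with Hoxa4 higher at least 14.6-fold and Hoxa7 at least 4.90-fold, and in 10 without control arrays 4 and 5 (0.011). Mesenchymal glioma markers were higher in 9 of 12 cases (adjusted p = 0.0913 with an estimated correlation), with the adhesion receptor Cd44 at 4.60. MHC class II and cytokines were higher in 7 of 15 cases (adjusted p = 0.0682 with an estimated correlation), with Ccl5 higher at least 8.35-fold. Matrix and invasion genes were higher in 7 of 19 cases (adjusted p = 0.41 with an estimated correlation), with Sparc at 4.13, and that call was lost even at the preset correlation without control arrays 4 and 5 (0.0589). Neural stem and radial glia genes were lower in 5 of 15 cases and higher in 3 (adjusted p = 0.41 with an estimated correlation), with the Notch target Hes5 at -3.71. All these counts were the same when adjusted over the list alone.

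The postnatal response comprised 2904 genes, 1739 higher and 1165 lower, with 2345 free of overlap between the groups. The share of rises was 59.9%, but 49.55% with every probe set on its own and 48.0% without a fold threshold, so the majority turned. Cdkn2a rose by 4.90 ± 0.24. Cdkn1a rose by 1.96 ± 0.42 and the intermediate filament gene Nes by 1.42 ± 0.36, but without control arrays 4 and 5 these fell short of 2-fold (0.90 and 0.59), and Nes also did without array 5 alone (0.94). Gfap, above background on 4 of 5 transformed arrays, fell by 3.01 ± 0.80, from control signals of 21873, 2843, 318, 976 and 1163, a call lost with the replicate number as a block (adjusted p = 0.063). Xist fell by 2.14 ± 0.12, from 35987 to 8151, while the Y-linked Eif2s3y read 3568 and 3272 and was not called. Pdgfra (-0.56 ± 0.19), Olig2 (-0.55 ± 0.06) and Sox2 (-0.74 ± 0.07) differed by less than 2-fold. Egfr was at -0.52 ± 0.19 by its representing probe set, with another probe set at 0.71 and 2 reading 7442 and 2947 in control and 67.6 and 64.8, within the background, in transformed cells. The mean of all, which includes these, gave -1.76. Without control arrays 4 and 5, 3002 genes changed, 2449 of them in common with the full set.

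Genes of chromosome 14 were lower as a group in transformed postnatal cells, a comparison made after the values were seen. Of 347 chromosome 14 genes with a mean signal over 500, 135 fell and 9 rose, with a median of -0.86, while the medians of the other 18 autosomes lay between -0.22 and 0.19. All 5 transformed arrays had a chromosome 14 median between -0.85 and -0.83 against the control mean. In the embryonic response the same genes had a median of 0.04. At any brightness, chromosome 14 held 150 of the 1165 genes called lower, or 12.9%. Of the genes with a mean signal over 500, 38.9% were called lower on chromosome 14, against 3.59% to 10.2% on the other autosomes.

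**Figure D2:**
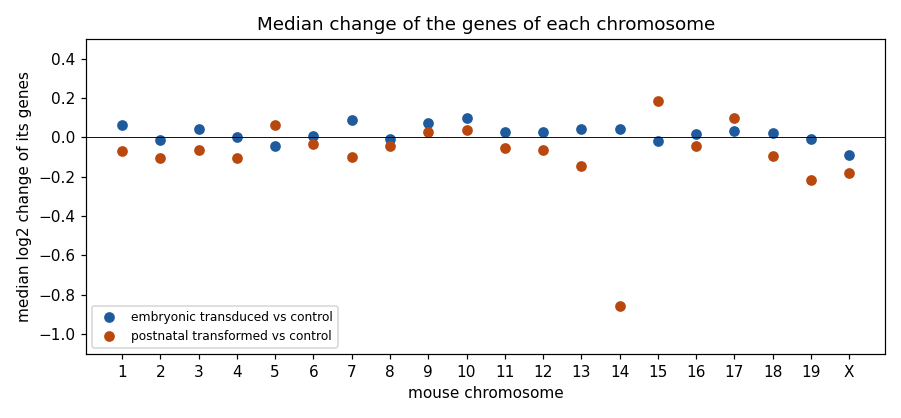
Median log2 change of the genes of each chromosome with a mean signal over 500, for the embryonic and the postnatal response; each point is 1 chromosome in 1 comparison. Chromosome 14 lies at -0.86 in the postnatal response and at 0.04 in the embryonic one, and the other autosomes lie between -0.22 and 0.19.

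The embryonic and postnatal responses shared a part of their genes. Of the genes changed in each, 499 were higher in both against 149.8 for independent lists, and 237 lower in both against 66.9. Opposite changes were found in 86 genes higher in embryonic and lower in postnatal cells (100.3 for independent lists) and in 155 of the reverse kind (99.8). The genes with the largest fitted rise in both were Mycn, Ifi27l2a, Ifi35, Lgals9 and Pdlim4. The interferon-induced Ifi35 rose by 5.97 ± 0.15 in postnatal cells and Lgals9 by 6.06 ± 0.26 in embryonic cells. Those with the largest fitted fall in both were the glutamate receptor Grm3, the transcription factor Zic1, Vit, Ralyl and Ttc9b, each at background in at least 1 modified group, so that their order is not known. In embryonic cells Zic1 was at -3.94, while Grm3 read 3313 and 122 and Ralyl 1323 and 128, each above background on 1 of 5 transduced arrays, and in postnatal cells Grm3, Zic1 and Ralyl fell at least 10.9-fold, 9.37-fold and 3.803-fold. Vit fell at least 12.1-fold and at least 7.88-fold, and Ttc9b fell at least 2.55-fold in embryonic cells and read 1533 and 82.2 in postnatal cells, above background on 1 of 5 transformed arrays. Across the 18193 genes the log2 changes correlated with r = 0.237 and Spearman rho = 0.172, where genes are not independent replicates.

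**Figure D3:**
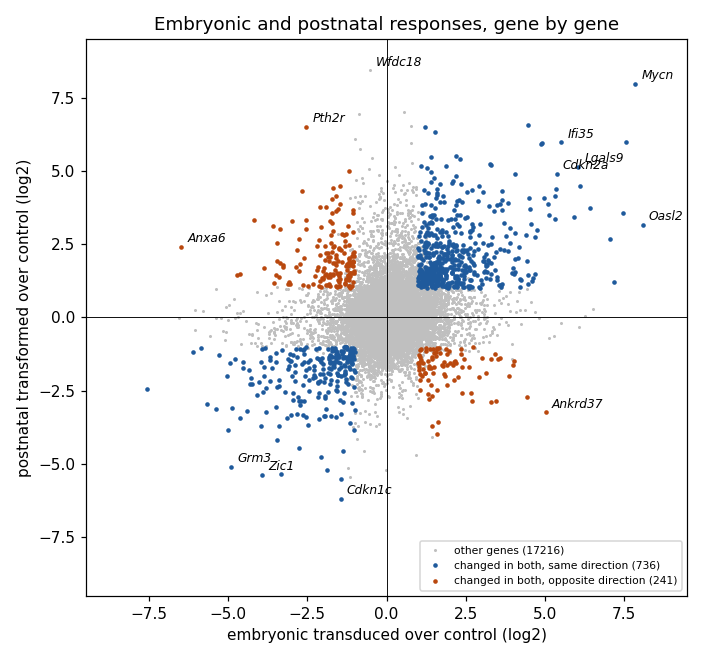
Log2 change of each gene in transduced embryonic cells (horizontal axis) and in transformed postnatal cells (vertical axis), each over its own control. Blue points are the 736 genes changed in both in the same direction, orange points the 241 changed in opposite directions, and grey points the rest; Mycn lies at 7.85 and 7.96.

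The difference between the responses was tested as an interaction, and 3475 genes passed, 1702 with a higher change in postnatal cells and 1773 with a lower one. That difference also holds any difference between transduction and transformation. The share with a higher change, 49.0% as deposited, was 56.3% after quantile normalization and 56.4% after 75th percentile centring, so the majority turned. Pth2r, Wfdc18, Anxa6, Syt4 and Cthrc1 had the largest fitted excess in the postnatal response. Anxa6 fell from 11108 to 133 in embryonic cells and rose from 1617 to 7303 in postnatal cells. Syt4 read 337 and 216 in embryonic cells and 397 and 46516 in postnatal cells. Ankrd37, the early growth response gene Egr3 (-7.17 ± 0.51), Col2a1, Otx1 and P4ha2 had the largest fitted deficit. Ankrd37 read 892 and 29423 in embryonic cells and 988 and 105 in postnatal cells, and P4ha2 read 94.0 and 8871 in embryonic cells, then 255.6 and 303 in postnatal cells. Pth2r, Wfdc18, Cthrc1, Col2a1 and Otx1 were below background on all arrays of at least 1 group, so the size of their difference is not known. Nor is that of Anxa6, Syt4, Ankrd37 and P4ha2 exact, each above background on 1 to 3 of 5 arrays of a group. Wfdc18 rose at least 124-fold in postnatal cells and read 140 and 93.7 in embryonic cells, and Col2a1 rose at least 18.9-fold in embryonic cells and read 44.0 and 29.7 in postnatal cells. The oligodendrocyte progenitor list differed upwards in 9 of 15 genes, 10 when adjusted over the list alone (adjusted p = 0.0377 with an estimated correlation), with Lhfpl3 at 5.42 ± 0.17 and Pdgfra at 3.14 ± 0.26. The neuron list differed upwards in 10 of 15 genes and downwards in 2, as when adjusted over the list alone (adjusted p = 0.00448 with an estimated correlation), with Gap43 at 6.11 ± 0.20. The stress list differed upwards in 5 of 15 genes, as when adjusted over the list alone (adjusted p = 0.0394 with an estimated correlation), with Ddit3 at 2.08 ± 0.18 but 0.65 for the mean of its probe sets. The interferon list differed downwards in 9 of 17 genes and upwards in 2, a call lost with an estimated correlation (adjusted p = 0.0981). The hypoxia list differed downwards in 9 of 17 and upwards in 1, and the immediate early list downwards in 8 of 12 (adjusted p = 0.0859 and 0.0669 with an estimated correlation). Only without postnatal control arrays 4 and 5 did the hypoxia list pass with an estimated correlation (adjusted p = 0.0297, 8 lower and 1 higher), as did that of Hox genes (0.048, against 0.111 with all arrays). Mitosis genes differed downwards in 3 of 19 cases, 0 when adjusted over the list alone (adjusted p = 0.781 with an estimated correlation), and in all 19 without postnatal control arrays 4 and 5 (0.013), where DNA replication did so in 18 of 21 (0.0233). The mitosis and DNA replication results without arrays 4 and 5 follow from setting those arrays apart for low proliferation genes. Whether those of the hypoxia and Hox lists do was not tested. Without those arrays the count was 3683, of which 3071 were in common. The median of all genes was -0.07 as deposited and 0.04 after quantile normalization.

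Before any modification, postnatal and embryonic control cells differed in Hox genes, which set position along the body axis. Of 24 Hox genes, 22 were lower in postnatal control and none higher, as when adjusted over the list alone (median -3.99, or -3.21 with 12 genes at their bound; adjusted p = 7.62e-06 with an estimated correlation). Hoxa9 was lower by at least 74.0-fold (mean 10999 against 44.1), Hoxa7 by at least 47.6-fold, Hoxc8 by at least 35.8-fold and Hoxb6 by at least 33.7-fold, and Fndc3c1 read 4297 and 87.7, above background on 2 of 5 postnatal control arrays. A second Hoxa9 probe set read 2240 in embryonic and 222 in postnatal control, a smaller difference. The largest fitted rises were in Scrg1 (4.90 ± 0.17), Brinp1 (mean signal from 229 to 5599), Sparcl1 (4.62 ± 0.25), the calcium-binding glial protein S100b (4.50 ± 0.51) and the growth factor Bmp4 (172 to 9384). Brinp1 and Bmp4 were above background on 3 of 5 embryonic control arrays. Hedgehog signalling fell in 7 of 10 genes, as when adjusted over the list alone (adjusted p = 0.0422 with an estimated correlation), with the transcription factor Gli3 at -2.69 ± 0.17 and the co-receptor Cdon at -2.63 ± 0.15, and Wnt targets in 3 of 11, also when adjusted over the list alone (0.0422), with Lgr5 at -2.12 ± 0.12 and Wif1 reading 1396 and 139, above background on 2 of 5 postnatal control arrays. Myelinating oligodendrocyte genes rose in 11 of 16 cases, as when adjusted over the list alone (adjusted p = 0.123 with an estimated correlation), with Ugt8a at 2.79 ± 0.22 and Myrf reading 146 and 4508, above background on 2 of 5 embryonic control arrays. Their mean log2 was 10.01, 10.03, 9.68, 10.98 and 11.14 on postnatal control arrays 1 to 5, and without arrays 4 and 5, 7 of 16 rose (0.0127). Oligodendrocyte progenitor genes were higher in 7 of 15 cases and lower in 1, as when adjusted over the list alone, with Pdgfra at 2.62 ± 0.19 and Sox10 at 3.16 ± 0.30, but the call was lost with an estimated correlation (adjusted p = 0.123). Without arrays 4 and 5, 4 of 15 were higher and 1 lower (0.126).

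The control comparison called 1925 genes, 884 higher and 1041 lower, and 1367 without postnatal control arrays 4 and 5, with 1183 in common. Of those 1367, 700 were higher and 667 lower, so the majority turned, as it did with every probe set on its own (51.65% higher) and without a fold threshold (51.2%). In the mitosis list 18 of 19 genes were called lower, 19 when adjusted over the list alone (adjusted p = 0.459 with an estimated correlation), for example Bub1 at -1.63 ± 0.42, and in DNA replication 11 of 21 (adjusted p = 0.484 with an estimated correlation), but without those arrays none of either list was called. The loss of these calls follows from setting those arrays apart for their low proliferation genes. Cdkn1a differed by 0.56 ± 0.42 with all arrays and by 1.62 without arrays 4 and 5. Age of origin, region of origin, culture and preparation cannot be separated in this comparison. Hox genes were lower in postnatal control. There 5 of 13 forebrain patterning genes were higher and none lower, a list call lost with an estimated correlation (camera adjusted p = 0.123). The difference therefore cannot be read as one of age alone.

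**Figure D4:**
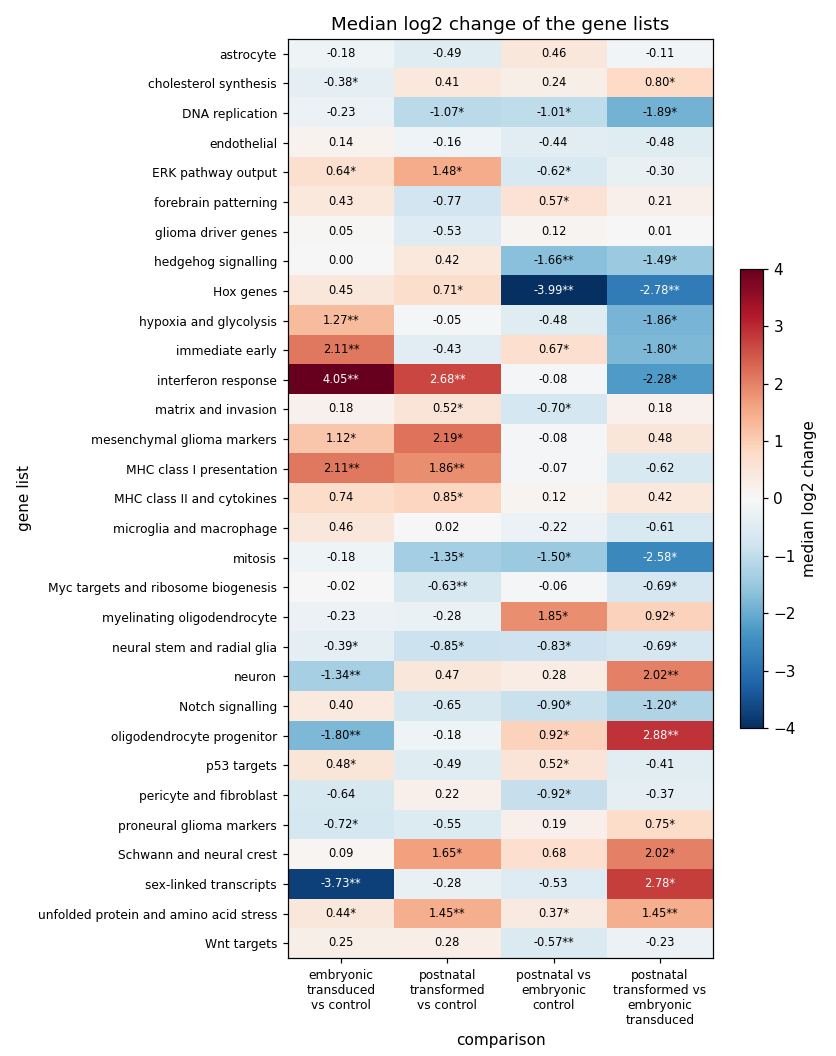
Median log2 change of the measured genes of each of 31 lists (rows) in the embryonic and postnatal responses and in the age comparisons of control and of modified cells (columns), with colour for the same value. A single asterisk marks an adjusted p under 0.05 at the preset correlation of 0.01, and a double asterisk one that also held with an estimated correlation, as for the interferon list at 4.05 and 2.68 (2.27 with genes at background at their bound).

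Among the modified cells, the postnatal group had higher oligodendrocyte progenitor and neuronal genes and lower Hox genes than the embryonic group. The labels call the postnatal group transformed and the embryonic group transduced, so age and kind of modification cannot be separated. In the progenitor list 11 of 15 genes were higher and none lower, as when adjusted over the list alone (adjusted p = 0.00991 with an estimated correlation), with Lhfpl3 at 6.51 ± 0.12 and Pdgfra at 5.77 ± 0.19. In the neuron list 11 of 15 were higher and 1 lower, 11 and 2 when adjusted over the list alone (adjusted p = 0.00277 with an estimated correlation), with Gap43 at 5.50 ± 0.14. Of 24 Hox genes 20 were lower and 1 higher, 21 lower and 1 higher when adjusted over the list alone (adjusted p = 0.0062 with an estimated correlation). In the stress list 9 of 15 were higher, as when adjusted over the list alone (adjusted p = 0.00637 with an estimated correlation), with Ddit3 at 3.19 ± 0.12. The largest fitted rises were in the cadherin Cdh19 (at least 51.3-fold), Serpina3n (at least 87.0-fold), Syt4 (mean signal from 216 to 46516), Wfdc18 (93.7 to 18375) and Cthrc1 (at least 42.5-fold). The largest fitted falls were in Hoxa9 (38495 to 75.4, and 9339 to 205 on its second probe set), Ankrd37 (29423 to 105), the stem cell surface gene Prom1 (20738 to 123), Hoxa10 (10752 to 105) and Hoxc10 (at least 35.3-fold). In embryonic transduced cells Syt4 was above background on 3 of 5 arrays and Wfdc18 on 1, and in postnatal transformed cells Hoxa10 was on 2 and Hoxa9, Ankrd37 and Prom1 on 1, so the order of these genes is not known. Hypoxia and glycolysis genes were lower in 11 of 17 cases and higher in 1 (adjusted p = 0.117 with an estimated correlation), with Pdk1 at -5.49 ± 0.25 and Pfkl at -3.83 ± 0.17. Notch signalling was lower in 7 of 14 genes and higher in 2 (adjusted p = 0.156 with an estimated correlation), with Nrarp at -4.93 ± 0.13 and Hes5 at -5.77 ± 0.27. All 19 mitosis genes were lower (adjusted p = 0.431 with an estimated correlation), with Mki67 at -2.79 ± 0.44. The mean log2 of that list was between 14.03 and 14.20 on embryonic transduced arrays and between 11.35 and 11.58 on postnatal transformed arrays. The estimated correlation and the standard error come from all 20 arrays. They thus also hold the spread within postnatal control, where arrays 4 and 5 read apart and which is not compared here. Altogether 4634 genes differed, 2135 higher and 2499 lower. The share of higher genes was 46.1% as deposited, 52.4% after quantile normalization and 50.04% after 75th percentile centring, around a median shift of all genes of -0.14 as deposited and 0.00 after quantile normalization. Across genes these log2 differences correlated with those between the controls at r = 0.422 and Spearman rho = 0.370. In both comparisons 1052 genes were changed with the same sign, against 246.7 for independent lists, and 156 with opposite signs.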

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

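The tests of the B1 repeat probe set were chosen after its values were seen, and 5 imprinted genes were added to the test for single samples after their values were seen.

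The embryonic and postnatal responses differed, by the interaction term, in 3475 genes. The 10 largest differences named, postnatal minus embryonic, were 9.02 for Pth2r, 8.94 for Wfdc18, 8.88 for Anxa6, 7.80 for Syt4 and 7.53 for Cthrc1, and -8.26 for Ankrd37, -7.17 for Egr3, -6.42 for Col2a1, -6.31 for Otx1 and -6.21 for P4ha2. The values of Pth2r, Wfdc18, Cthrc1, Col2a1 and Otx1 are fitted to groups below background on all arrays, depend on the offset and are neither exact nor bounds. Those of Anxa6, Syt4, Ankrd37 and P4ha2 also depend on it, with a group in which 2, 3, 1 and 1 of 5 arrays were above background. Among gene lists the median fitted difference was 3.79 for sex-linked transcripts, 1.80 for oligodendrocyte progenitor, 1.69 for neuron, 1.55 for Schwann and neural crest, 0.87 for Hox genes, 0.82 for unfolded protein and amino acid stress, 0.76 for ERK pathway output, 0.72 for proneural glioma markers, 0.54 for cholesterol synthesis and 0.39 for matrix and invasion. It was -2.16 for immediate early, -1.77 for interferon response, -1.37 for hypoxia and glycolysis, -1.01 for DNA replication, -0.91 for p53 targets and -0.55 for Myc targets and ribosome biogenesis. With genes at background at their bound in each response, the median was 3.65 for sex-linked transcripts, 1.31 for Schwann and neural crest, 0.89 for ERK pathway output, 0.61 for matrix and invasion and -2.11 for interferon response, and the other 11 did not move. Of these 16 lists, only oligodendrocyte progenitor, neuron and the stress list held with an estimated correlation. The DNA replication call was lost without postnatal control array 1, 2 or 3 (camera adjusted p = 0.069, 0.0732 and 0.0836) and the matrix and invasion call without embryonic transduced array 5 (0.0542) or without postnatal control arrays 4 and 5 together (0.0838).

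A control probe set for the B1 repeat, a short interspersed element, is outside the gene comparisons. Its mean signal was 15602 in embryonic control, 47664 in embryonic transduced, 31336 in postnatal control and 119053 in postnatal transformed. The ratio to control was 3.05 in embryonic and 3.799 in postnatal cells, with all 5 modified arrays above all 5 controls (exact permutation test, two-sided, p = 0.00794 for each, the smallest 5 against 5 can give; adjusted p = 0.0119 over 12 tests). The signal also differed between the controls (ratio 2.01) and between the modified groups (2.50) with the same p.

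A single array lay far from the other 4 of its group, by the gap to its nearest neighbour over the range, in 23 of 429 groups tested, where chance gives about 1 in 20, or 21.45. In embryonic transduced array 5 the interferon list mean was high (0.789), and Cdkn1a (0.943), Prom1 (0.839), Ndrg1 (0.774), Hoxc8 (0.719) and Pcolce (0.716) were low. Cdkn1a read 22405 there against 28901 to 29353 on the others. Other embryonic transduced arrays stood apart for B2m (0.839), Dll3 (0.781) and Kcnq1ot1 (0.753). Embryonic control arrays stood apart for Grb10 (0.83), Sparc (0.821), Klf4 (0.801), Kif11 (0.793), Vegfa (0.779), Egr2 (0.763) and Egr1 (0.713), the last 3 high on array 3. Postnatal transformed arrays stood apart for Cdon (0.855), Nrarp (0.853), Emx2 (0.759), Gad1 (0.758), Hes5 (0.737), Ifi35 (0.737) and, as a list mean, DNA replication (0.739). Postnatal control had no such gene. The measure does not single out 2 arrays that lie together, as postnatal control arrays 4 and 5 did for Mki67 but not for Mycn. Whether this accounts for the lack of such genes was not tested.

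Each count of changed genes was set against 100 splits of the same arrays into groups of the same sizes, the real one included. Only 1 of 100, the real one, gave as many genes in each of the 5 comparisons. Every other split mixes arrays of the groups compared, so this shows only that arrays of a group resemble each other. It cannot exclude a chance difference between cultures, since the samples of a group may be technical. The embryonic response called 2611 genes against at most 502 in another split, the postnatal response 2904 against 695, the difference of responses 3475 against 2190, the control comparison 1925 against 728 and the modified cells 4634 against 2.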

How the results depend on the processing

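The alternatives that left out postnatal control arrays 4 and 5, used the largest offset, left out genes below background or left out chromosome 14 were chosen after seeing the data. No called gene or list reversed under the alternatives run for genes and lists, which were not all of them. The majority direction was not stable. It turned for the difference of responses and the modified cells with both other scalings and with treat, and for the difference also without chromosome 14 and without embryonic transduced array 5 or postnatal control array 1 or 2. For the control comparison it turned without postnatal control arrays 4 and 5, and for that and the postnatal response with every probe set on its own and without a fold threshold. Leaving out each array in turn gave 2517 to 2632 genes for the embryonic response, 2786 to 2928 for the postnatal one, 3407 to 3551 for their difference, 1603 to 2110 for the control comparison and 4539 to 4691 for the modified cells, with r between the responses from 0.2293 to 0.2414 and 708 to 742 genes shared in direction. In the same order, dropping the dimmest 50% of genes gave 1215, 1505, 2065, 964 and 2563, with r 0.2533 and 332 shared, since fewer genes were tested. Every probe set on its own gave 6161, 6827, 8642, 3977 and 11159, since more were tested. Without a fold threshold the counts were 7162, 7692, 7083, 5830 and 9479, and when tested against 2-fold (treat) 1086, 1164, 1322, 470 and 2539, by construction. The largest offset, which shrinks dim changes, gave 1702 for the embryonic response, 1128 for the control comparison and 417 shared. The r was 0.2233 after quantile normalization, 0.2705 without the dimmest 30%, 0.2218 with the mean of all probe sets and 0.224 without postnatal control arrays 4 and 5, and the cause was not tested. With an estimated correlation 56 of 77 list calls were lost. Of 689 values of named genes, 31 lost their call and 7 gained one with the mean of all probe sets, and 40 lost it with the largest offset. Replicate numbers did not pair the arrays, since r between like-numbered arrays ranged from -0.209 to 0.242 in embryonic cells and from -0.0522 to 0.0633 in postnatal cells. Signal over background limits dim genes, for which only a lower bound of the fold is known.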

Other observations

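The tests on chromosome 14 (apart from that along its length), Mycn, the Y-linked genes and the imprinted genes were chosen after the result was seen.

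Several gene groups not described above passed at the preset correlation. Mesenchymal glioma markers were higher in 6 of 12 cases in transduced embryonic cells, also when adjusted over the list alone, a call lost at an adjusted p = 0.205 with an estimated correlation. Genes of cholesterol synthesis had 1 of 15 lower there (adjusted p = 0.607 with an estimated correlation), and targets of p53 5 of 17 higher and 1 lower (adjusted p = 0.408 with an estimated correlation). Between the control groups, forebrain patterning genes were higher in 5 of 13 cases in postnatal cells and none lower (adjusted p = 0.123 with an estimated correlation), with Emx2 reading 163 and 2061, above background on 2 of 5 embryonic control arrays. Matrix and invasion genes were lower in 9 of 19 (adjusted p = 0.154 with an estimated correlation), with Tnc at -3.89. Without postnatal control arrays 4 and 5 the lists of neural stem and radial glia, 4 of 15 lower, of p53 targets, 5 of 17 higher, and of unfolded protein and amino acid stress, 2 of 15 higher, held in that comparison (adjusted p = 0.0279, 0.0279 and 0.0228 with an estimated correlation). Markers of microglia and macrophages were called higher in 2 of 15 cases in the embryonic and 3 of 15 in the postnatal response, and neither list passed (camera adjusted p = 0.339 and 0.432).

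Imprinted genes, expressed from a single parental copy, were among those changed in the modified cells. Their list was written after the results were seen, following 31 fixed lists, and its genes were chosen after their values were seen, so the tests on it do not show that imprinted genes change more often than others, which stays open. Of 29 measured genes, 18 or 62.1% were called in at least 1 response, against 24.9% of 18164 other genes (Fisher's exact test, two-sided, p = 2.49e-05), and 1 of 10000 random lists matched on level had as many, with a mean of 7.87. The direction was mixed, with 6 higher and 8 lower in embryonic and 2 higher and 7 lower in postnatal cells. The receptor adaptor Grb10 fell by 3.60 ± 0.11 in embryonic and rose by 3.11 ± 0.11 in postnatal cells, Nnat fell by 3.56 ± 0.07 in embryonic cells, Ndn fell by 1.38 ± 0.06 and 2.89 ± 0.06, and Kcnq1ot1 rose by 3.30 ± 0.15 in embryonic and fell by 1.41 ± 0.15 in postnatal cells. Methylation was not measured.

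Genes of chromosome 14 were lower in postnatal transformed cells by a median of -0.86. Low cycling of the cells was argued against, since postnatal control arrays 4 and 5, with low mitosis genes, had no such shift and the lowest control array median against embryonic control was 0.0122. A chance set of genes was argued against too. The chromosome had been picked as the most extreme of 20, so the genes were shuffled among all 20 within brightness, and in 0 of 10000 shuffles did any chromosome have a median as far from 0 (furthest 0.226), although genes are not independent. Loss of 1 copy along the whole chromosome, which would give -1, is a candidate explanation, since the highest median among 5 consecutive sections by gene order in assembly GRCm38.p6 was -0.719. DNA was not measured, and whether such a loss came with transformation or with the culture stays untested.

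The Mycn signal rose over 100-fold in both modified groups on 1 of 3 probe sets. A rise of the whole transcript was argued against, since the highest change of the other 2 was 1.26, and so was amplification of the region, since the 4 nearest measured genes (Smc6, Cyria, Ddx1 and Nbas) had a median of -0.101 over both responses. An introduced or retroviral sequence under that probe set may be the source, since its signal was alike in both modified groups, with a ratio of 1.06, but the labels name no such sequence and it cannot be told apart from other causes here.

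Y-linked Eif2s3y, Kdm5d and Uty and also Xist were lower in embryonic transduced cells. A general loss of signal at that brightness was argued against, since 0.0635% of 1575 other genes of the same control level fell as far as the fitted median of the Y-linked genes, and their own median was 0.13. Female cells with an inactive X chromosome stay open. The fall of Xist (-2.44) had been set as evidence against them, but Xist stayed above background on all 5 transduced arrays. Xist also fell by 2.14 in postnatal transformed cells, where no Y-linked gene was called lower. Whether the share of female cells changed there is not known, so that fall does not show that Xist falls without a change of sex. Loss of the Y chromosome may account for the pattern and stays open too, since Uty above background on 3 of 5 arrays goes against a complete loss, but its mean of 208 lay within the range of the array background levels, 107 to 221. Both control groups had Xist and Eif2s3y above background on all 5 arrays. The mean signals were 12495 and 4156 in embryonic control and 35987 and 3568 in postnatal control. Cells of both sexes may thus have been present in the control samples. Whether the transduced cells came from starting cells of a different sex stays untested.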
